A study of Mus musculus with 6 samples.

How the data were processed

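Liver RNA of 6 male C57BL/6J mice was measured on Affymetrix whole-transcript arrays, 1 array per mouse. The labels name 2 groups of 3 mice. HKO mice carry a floxed Slug gene (symbol Snai2, a zinc finger transcription factor of the Snail family) together with albumin-CreERT2, a tamoxifen-inducible Cre recombinase driven by the albumin promoter, so that the gene is removed in hepatocytes. Con mice are their floxed littermates. Whether Con mice carried the Cre transgene, and how recombination was induced, are not given in the sources used here. Per the labels' protocols, the mice were put on a high fat diet with 60% of calories from fat at 8 weeks of age and kept on it for 11 weeks, RNA was taken from matched parts of the liver, and biotin-labelled cDNA was made from 400 ng of total RNA.

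The authors deposited log2 values, 1 per probe set and array, made with RMA in R 3.3.0 per the submitters' processing notes. RMA corrects the background, sets the distributions of all arrays equal and summarises the probes of a probe set, so differences are relative to the array's overall distribution and changes of dim genes are compressed. Any further filter and the genome build of the array design are not given in the sources used here, and no coordinates are printed for that reason. The deposited log2 values run from 0.56 to 12.56, and the median over genes rounds to 3.95 on every array. Arrays have no read depth; the number of arrays limits the precision.

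The table holds 41345 probe sets. A platform annotation gave 1 gene to 23521 of them, several to 1814 and none to 16010. Of the probe sets with 1 gene, 23328 were found by Entrez identifier in a RefSeq gene table of the assembly GRCm38.p6, which changed 0 symbols, and 193 were not found there and kept the annotation's symbol. Each gene was represented by its probe set with the highest mean over the 6 arrays, which left 22180 genes, 1082 of them with more than 1 probe set. No filter on low values was applied. Probe sets with several genes or none stayed out of the comparison and were tested on their own.

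HKO was compared with Con using limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the only term), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p 0.05. Standard errors of single genes are limma's moderated ones. Those of list or family means, and of differences between lists, are taken over the member genes as if independent. They do not measure the spread between mice. For Snai2 and for the mean of the lipogenesis list, an exact two-sided permutation test was added; with 3 against 3 arrays its smallest possible p is 0.1. Before the data were examined, 40 gene lists (pathways and cell type markers) were fixed, of which 39 had at least 5 measured genes. They were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the 39 lists, and again with the correlation estimated from the data and with limma's fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

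The genes named were set by a rule also fixed before the data were examined: Snai2, the 10 genes with the largest change in each direction among those past the threshold (predicted genes and clones passed over, 5 in all), in each list up to 4 members past the threshold or otherwise the 2 members with the lowest p, and 5 lipogenic genes in every case. Genes outside it are said to be chosen after their values were seen. For several lists, some or all of the members that the rule picked are not printed, so the rule alone does not settle which of them appear. The alternatives tried were a second quantile normalization, centring of arrays, 2 filters on low values, other treatments of probe sets, a variance trend, a robust fit, array weights, the replicate number as a block, other thresholds, a test without shared variance, leaving out each array, and the other list tests.

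The steps were tested on simulated data. In 20 simulations over 22180 genes with 200 changed genes, the HKO against Con comparison recovered 14.5% of genes changed by 0.5 log2 units, 67.1% of those changed by 1 and 95.4% of those changed by 2, and 4.04% of calls were false. In simulated lists of 18 genes drawn without correlation between genes, a shift of 0.3 was called in 100% of lists with the preset correlation and in 95% with the estimated one, and 0.735% of unshifted lists were called with the preset correlation. Lists of co-regulated genes depart from that simulation. For single genes, the simulation shuffled the spread across genes and gave dim genes the full change. Any tie between level and spread on the real arrays was thus removed, and the shares recovered and falsely called hold for that setting only.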

Results

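Gene expression was measured in liver pieces of 3 HKO mice, which lack Slug in hepatocytes, and 3 Con littermates, all on a high fat diet. The comparison asks which liver transcripts differ when hepatocytes lack this transcription factor during high fat feeding. The 6 arrays were closely alike. Correlations over all genes lay between 0.989 and 0.992 within groups and between 0.986 and 0.988 across groups. The first principal component held 33.4% of the variance and separated the groups. Of 22180 genes, 4034 (18.2%) had HKO and Con values that did not overlap, where chance gives 10%.

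Snai2, the targeted gene (probe set 17323192), was lower in all 3 HKO arrays. Its log2 value was 7.61 ± 0.19 (SD, n = 3) in Con and 5.18 ± 0.54 (SD, n = 3) in HKO, a log2 change of -2.43 ± 0.25 (SE), or 5.39-fold lower, with a limma adjusted p of 0.0145. The Con arrays held 7.74, 7.69 and 7.39 and the HKO arrays 4.62, 5.23 and 5.69. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. Where the floxed part of the gene lies relative to the probes is not given in the sources used here, so the remaining signal in HKO cannot be read as intact transcript. The adjusted p of Snai2 was 0.0758 without Con replicate 1, 0.0927 without Con replicate 2 and 0.0621 without HKO replicate 2, with the change at -2.36 or below in each case, and 0.0540 with the replicate number as a block.

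Livers of HKO mice had more transcript of the transporter Slco1a1, the cytochrome P450 Cyp2c54 and the growth factor binding protein Igfbp2, and less of the cytochrome P450 Cyp2b13, the surface protein Ly6d and the lipid droplet protein Cidea. Of the 22180 genes, 45 passed adjusted p 0.05 in limma, 20 higher and 25 lower in HKO, and the array values of each of the 45 differed by at least 1.5-fold. At an unadjusted p under 0.05, 1177 genes were higher and 1455 lower. The count depends on the arrays, the design, the choice of probe sets and the variance model. It was 5 without Con replicate 1, 4 without Con replicate 2, 25 without HKO replicate 1, 6 without HKO replicate 2 and 16 without HKO replicate 3, 3 with the replicate number as a block (0 higher, 3 lower), 4 with every probe set tested on its own (0 higher, 4 lower), 215 with a variance trend and 0 with a test that shares no variance between genes. Of the 10 largest changes in each direction, Ly6d, Tubb2a, Anxa2 and Gprc5b passed without each of the 6 arrays in turn, and each of the others missed adjusted p 0.05 without at least 1 array.

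**Figure D1:**
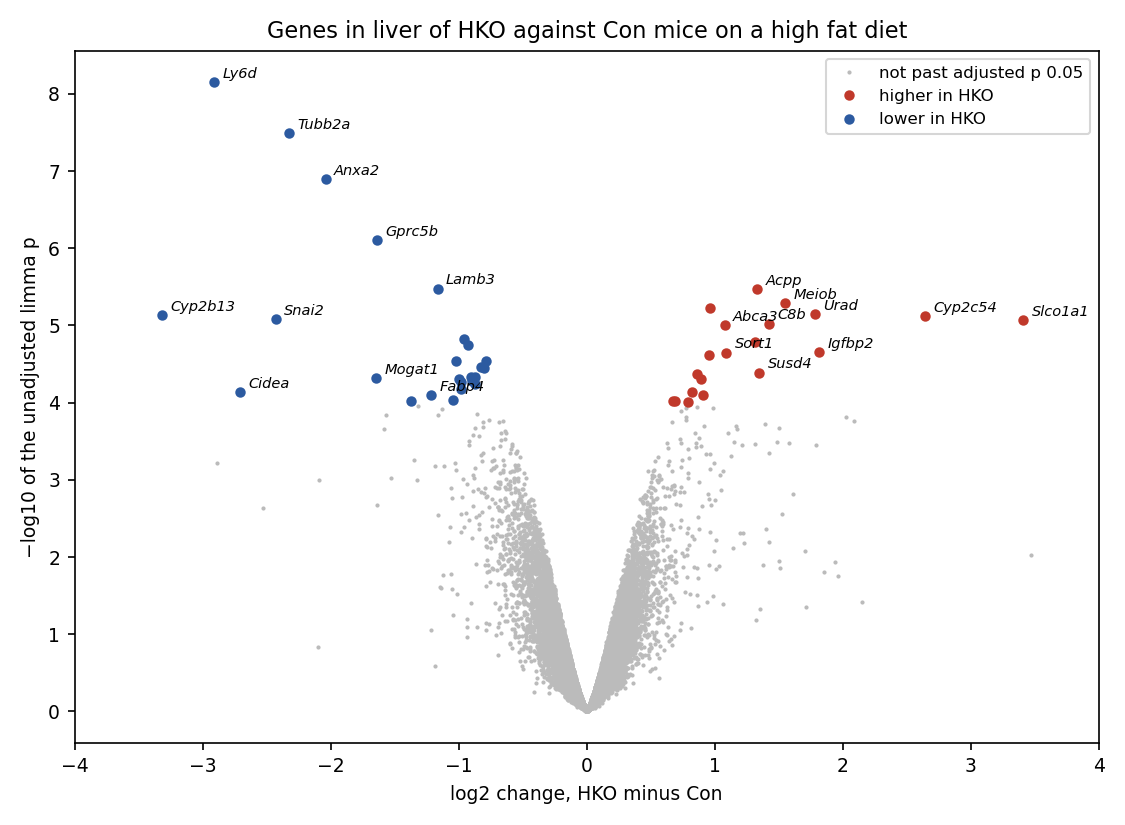
Each point is 1 of 22180 genes; the x axis is the log2 change from Con to HKO and the y axis -log10 of limma's unadjusted p, with 3 arrays per group. The 20 genes past adjusted p 0.05 that were higher in HKO are red, the 25 lower ones blue, and named genes carry their symbols.

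Among the genes that rose, Slco1a1, an organic anion transporter of the hepatocyte membrane, had the largest change, 3.41 ± 0.35 on the log2 scale (10.6-fold, adjusted p = 0.0145), from 5.83 ± 0.79 (SD, n = 3) in Con to 9.25 ± 0.28 in HKO. Cyp2c54, a cytochrome P450, rose by 2.65 ± 0.27 (6.26-fold, adjusted p = 0.0145). Igfbp2, which binds insulin-like growth factors, rose by 1.82 ± 0.21, and Urad, an enzyme of urate breakdown, by 1.78 ± 0.18. C8b, a component of the terminal complement complex, rose by 1.43 ± 0.15. Sort1, a sorting receptor that handles lipoproteins, rose by 1.09 ± 0.13, while its second, dim probe set (mean level 2.43) stood at 0.22. Abca3, a lipid transporter, rose by 1.08 ± 0.11. Meiob (1.55), Susd4 (1.35) and Acpp (1.33) complete the 10 largest log2 changes upward. All of these genes had higher values in all 3 HKO arrays than in any Con array.

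Among the genes that fell, Cyp2b13, a cytochrome P450 with higher expression in female liver, went from 7.20 ± 0.52 (SD, n = 3) in Con to 3.88 ± 0.60 in HKO (adjusted p = 0.0145). Ly6d, a membrane-anchored protein of the Ly6 family, had the lowest adjusted p, 0.000156, and went from 7.77 ± 0.18 (SD, n = 3) in Con to 4.86 ± 0.08 in HKO (7.51-fold lower). Tubb2a, a beta tubulin, changed by -2.32 ± 0.12 (adjusted p = 0.000356), and Anxa2, a calcium-dependent membrane-binding protein, by -2.04 ± 0.12 (adjusted p = 0.00094). Both Cidea and Mogat1 fell: Cidea went from 6.28 to 3.58, and Mogat1, a monoacylglycerol acyltransferase, from 5.35 to 3.71. Gprc5b (5.53 and 3.89), the fatty acid binding protein Fabp4 (-1.22) and the laminin chain Lamb3 (-1.17) complete the 10 largest changes downward in the array values, with Snai2 among them. Each of these genes was lower in all 3 HKO arrays than in any Con array. The HKO means of Cyp2b13 (3.88), Cidea (3.58), Mogat1 (3.71) and Gprc5b (3.89) lay below the median over genes (3.95) and are not shown to be above background, so their means are given and the size of their change is left open.

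**Figure D2:**
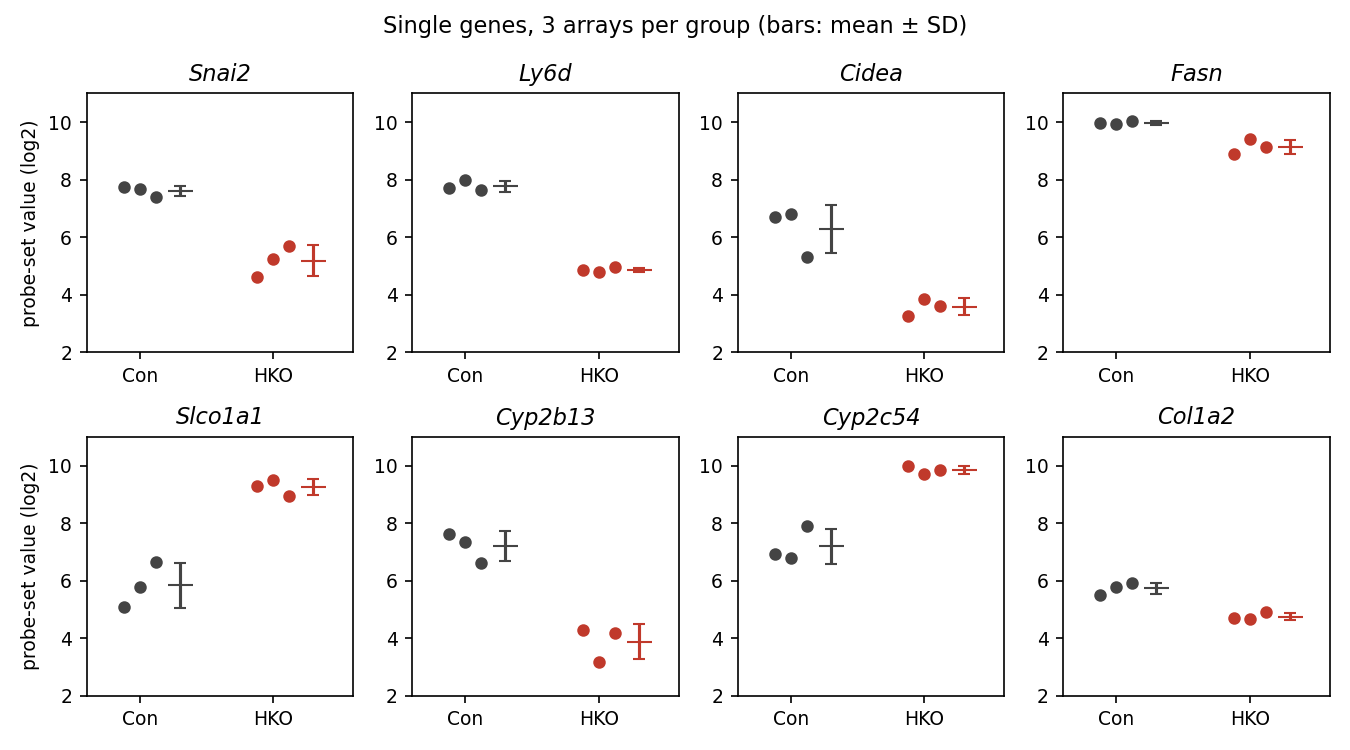
Log2 probe-set values of 8 genes in the 3 Con arrays (grey) and 3 HKO arrays (red); bars give the mean and SD of each group and points the single arrays. Snai2, Ly6d, Cidea, Cyp2b13 and Col1a2 passed adjusted p 0.05 downward, Slco1a1 and Cyp2c54 upward, and Fasn, at an adjusted p of 0.0763, did not pass.

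The gene lists showed lower values in HKO for lipid storage and synthesis, extracellular matrix and infiltrating macrophages, and higher values for male-biased, bile acid and cholesterol synthesis genes. Of the 39 lists tested, 18 passed adjusted p 0.05 in limma's camera with the preset correlation, 6 higher and 12 lower. With the correlation estimated from these arrays, 0 of the 39 passed (6 had an unadjusted p under 0.05). The adjusted p with an estimated correlation is given for that reason beside each list that passed. In limma's fry 5 lists passed, all lower in HKO. They were unfolded protein response (adjusted p = 0.0233), cell cycle (0.0308), and extracellular matrix, oxidative stress and mesenchymal genes (each 0.0479). Fry did not call lipogenesis (adjusted p = 0.114), triglyceride (0.0755), monocyte-derived macrophage, male-biased and bile acid (each 0.0561) or cholesterol lists (0.302).

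Genes of de novo lipogenesis, the synthesis of fatty acids from acetyl-CoA, were lower in HKO. The mean log2 change of the 19 measured genes was -0.30 (camera adjusted p = 6.56e-06; adjusted p = 0.387 with an estimated correlation; exact two-sided permutation p of the list mean 0.1, the smallest possible), and the mean was below that of every Con array in all 3 HKO arrays. Without HKO replicate 1 the mean was -0.19 (adjusted p = 0.00554). Over all genes 0 of the 19 passed, and 10 fell when adjusted over the list alone, while 16 had lower and 3 higher mean values. Fasn, fatty acid synthase, had a log2 change of -0.84 ± 0.14 (adjusted p = 0.0763 over all genes), and Pgd, an enzyme that supplies NADPH, -0.58 ± 0.11 (0.113). The carboxylase Acaca was at -0.41 (0.184), Acly at -0.43 (0.268), the transcription factor Srebf1 at -0.64 (0.254) and the desaturase Scd1 at -0.28 (0.387).

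Genes of triglyceride synthesis and lipid droplets had a mean log2 change of -0.53 over 22 measured genes (camera adjusted p = 1.09e-05; adjusted p = 0.288 with an estimated correlation) and a median of -0.22. Over all genes 2 fell, Cidea and Mogat1, 0 rose and 20 did not pass. Cidec, a lipid droplet protein chosen after its values were seen, was at -2.89 (adjusted p = 0.107), and these 3 genes hold most of the mean. Adjusted over the list alone, 9 fell and 1 rose. Cholesterol synthesis genes went the other way, with a mean of 0.59 over 19 genes (camera adjusted p = 5.07e-07; adjusted p = 0.450 with an estimated correlation). None of these passed singly, with 0 over all genes and 0 adjusted over the list alone; at an unadjusted p under 0.05, Tm7sf2, a sterol reductase, stood at 0.96 ± 0.25 and the regulator Srebf2 at 0.53 ± 0.17. The arrays differed widely in this list. HKO replicate 2 lay 1.21 above the Con mean, HKO replicate 3 lay 0.56 above it, HKO replicate 1 lay 0.02 above it and Con replicate 3 lay 0.28 above it. Without HKO replicate 2 the mean was 0.29 (adjusted p = 0.00111).

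Bile acid synthesis and transport genes had a mean log2 change of 0.32 over 22 genes (camera adjusted p = 2.20e-05; adjusted p = 0.288 with an estimated correlation). The median was 0.20. Slco1a1 rose over all genes, and 5 genes rose when adjusted over the list alone. Slco1a1 (3.41) holds a large part of the mean, and it and Cyp7b1 also belong to the male-biased list, so these lists are not independent. Lists of fatty acid oxidation (-0.04), gluconeogenesis and amino acid catabolism (-0.06), insulin signalling (-0.000681), lipoprotein metabolism (-0.02) and the mitochondrial respiratory chain (-0.03) did not pass, and did not pass without any 1 array. Their means moved widely then: gluconeogenesis from -0.16 without HKO replicate 1 and -0.11 without Con replicate 3 to -0.00343 without HKO replicate 2, fatty acid oxidation from -0.07 without HKO replicate 3 to 0.000532 without HKO replicate 1, and insulin signalling from -0.03 without HKO replicate 1 to 0.01 without HKO replicate 3. The lipoprotein mean ran from -0.06 without HKO replicate 2 to 0.00594 without HKO replicate 1, and the respiratory chain mean from -0.06 without HKO replicate 1 to 0.00675 without HKO replicate 3. A mean near 0 can hide members that change in opposite directions. In fry's mixed test, which counts changes either way, 28 of the 39 lists passed. Among them were lipoprotein (adjusted p = 0.00188), fatty acid oxidation (0.00516), gluconeogenesis (0.0163) and insulin signalling (0.0374), but not the respiratory chain (0.298). Within the insulin signalling list Irs2, an insulin receptor substrate, was at 0.88 ± 0.23 (adjusted p = 0.209) and Grb10, an adaptor that binds the insulin receptor, at -0.43 ± 0.13. In the lipoprotein list Apoa4 was at -0.92 ± 0.23 (adjusted p = 0.192). Glycolysis and hexose uptake genes were lower (-0.17 over 10 genes, camera adjusted p = 0.0069; adjusted p = 0.288 with an estimated correlation), with 0 genes past the threshold over all genes and 0 adjusted over the list alone.

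Genes known to be higher in male than in female liver were higher in HKO, all of whose mice were male as were the Con mice. The mean log2 change was 1.08 over 16 genes (camera adjusted p = 9.96e-10; adjusted p = 0.280 with an estimated correlation). Slco1a1 and Susd4 rose over all genes, and 10 rose when adjusted over the list alone. Female-biased genes went both ways. Over 18 genes the mean was -0.29, the median 0.08 and the camera adjusted p 0.642; Cyp2b13 fell over all genes, and when adjusted over the list alone 3 rose and 6 fell. Members of the Cyp2c, Cyp2b, Cyp4a and Mup families are similar in sequence, and probes can take signal from a near copy. Xenobiotic metabolism genes did not pass as a list (mean 0.13, median -0.10; mean 0.08 without HKO replicate 1), while Cyp2c54 and Cyp2c50 (0.96 ± 0.09) rose. The circadian list did not pass (0.09; 0.10 and adjusted p = 0.0360 without Con replicate 3, 0.05 without Con replicate 1, 0.04 without HKO replicate 1), with Usp2, a deubiquitinating enzyme, up by 0.69 ± 0.10 (adjusted p = 0.0483).

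Extracellular matrix genes fell as a list, with a mean log2 change of -0.61 over 21 genes (camera adjusted p = 1.08e-12; adjusted p = 0.206 with an estimated correlation). Col1a2, a chain of type I collagen, fell over all genes (-0.98 ± 0.13, adjusted p = 0.0415), while its second, dim probe set (mean level 2.70) stood at -0.18. Adjusted over the list alone 15 genes fell, and 20 of the 21 had lower mean values. Markers of monocyte-derived and lipid-associated macrophages were lower by the same mean, -0.61 over 11 genes (camera adjusted p = 8.46e-07; adjusted p = 0.280 with an estimated correlation). Itgax, an integrin of dendritic cells and recruited macrophages, fell (adjusted p = 0.028), from 4.44 to an HKO mean of 3.42, which is not shown to be above background, and 7 fell when adjusted over the list alone. Stellate cell markers had a mean of -0.22 and a median of -0.13 (camera adjusted p = 0.02; adjusted p = 0.423 with an estimated correlation), with Pdgfrb at -0.73 ± 0.19, and 4 of 12 fell when adjusted over the list alone and 0 over all genes. The stellate call was lost without Con replicate 2 (adjusted p = 0.115) or HKO replicate 1 (adjusted p = 0.139).

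Most other cell type lists did not pass. Kupffer cell markers had a mean of -0.11 (camera adjusted p = 0.284), sinusoidal endothelial markers -0.07 (0.611), cholangiocyte markers -0.11 (0.255), T and NK cell markers -0.19 (0.0617), neutrophil markers -0.15 (0.0784), hepatocyte markers 0.06 (0.168) and exocrine pancreas markers -0.01 (0.998). The adipocyte list did not pass (mean -0.09, median 0.09), although its member Fabp4 fell. B and plasma cell markers had a mean of 0.33 and a median of 0.06 over 8 genes (camera adjusted p = 0.0376; adjusted p = 0.288 with an estimated correlation), with 2 genes past the threshold adjusted over the list alone and 0 over all genes; Jchain, the joining chain of secreted antibodies, had means of 3.39 in Con, not shown to be above background, and 4.81 in HKO, and Ighm was at 0.97 ± 0.22. Of 6 other Ighm probe sets, 4 had log2 changes from 0.51 to 1.32 and 2 stood at -0.04. The B and plasma cell call was lost without Con replicate 1 (adjusted p = 0.0737), Con replicate 2 (0.113) or HKO replicate 1 (0.0525). Leaving out 1 array moved other means both ways. Kupffer markers stood at -0.05 without Con replicate 1, -0.06 without HKO replicate 3 and -0.21 without Con replicate 3, where they passed (adjusted p = 0.0114). T and NK cell markers stood at -0.10 without Con replicate 1, -0.12 without Con replicate 2 and -0.34 without Con replicate 3, where they passed (0.000448). Neutrophil markers stood at -0.10 without Con replicate 2 and passed without Con replicate 3 (-0.20, 0.0135) or HKO replicate 3 (-0.21, 0.0153). The hepatocyte mean was 0.00484 and the adipocyte mean -0.06 without HKO replicate 1, the sinusoidal mean -0.04 without Con replicate 2, and the pancreas mean -0.05 without HKO replicate 3 and 0.04 without HKO replicate 2. Of the red blood cell list only Slc4a1 was measured (0.16), and the list was not tested.

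**Figure D3:**
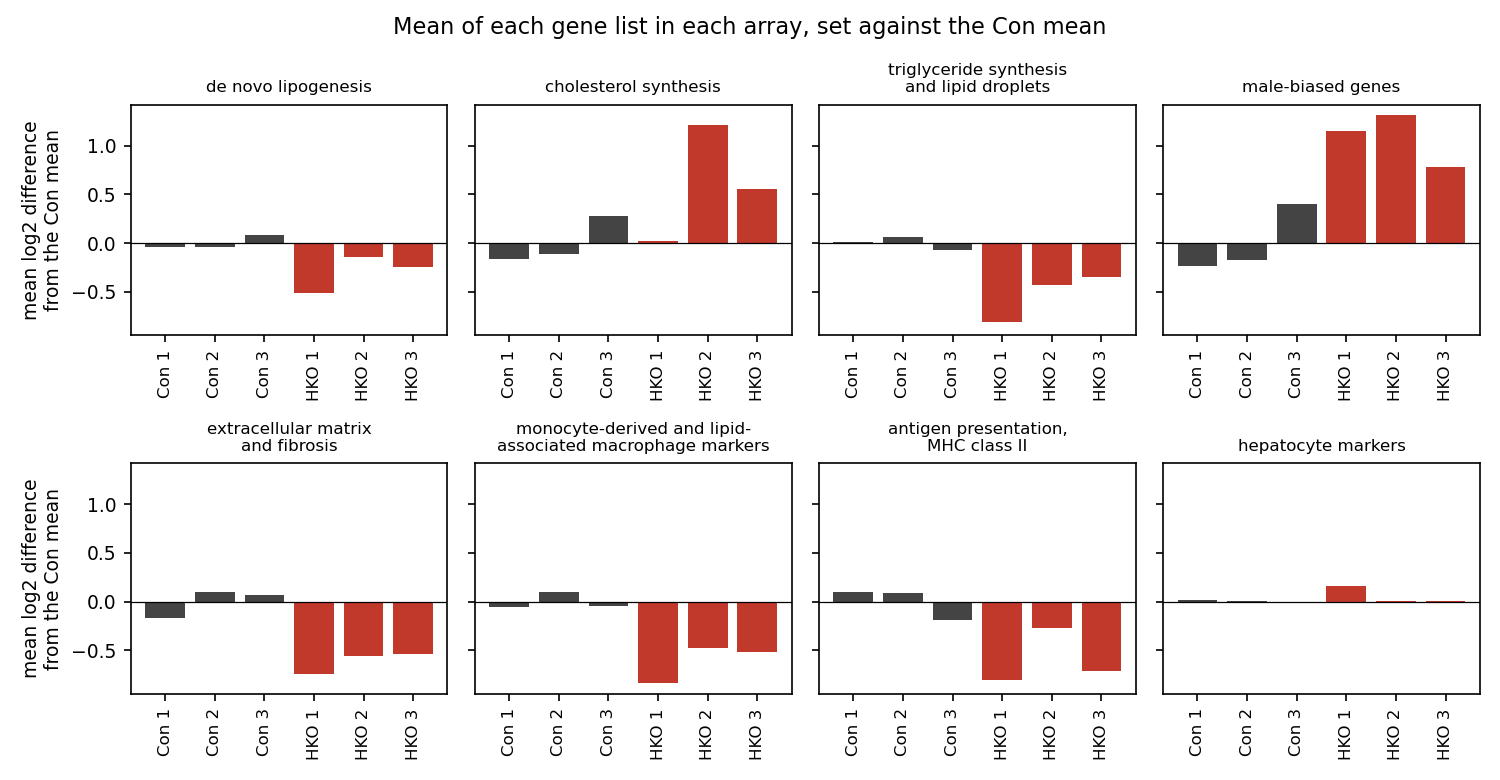
Bars give, for 8 gene lists, the mean log2 difference of each array from the Con mean (y axis), in the 3 Con arrays (grey) and 3 HKO arrays (red). The matrix list lies between -0.74 and -0.54 in the HKO arrays, while the cholesterol list runs from 0.02 in HKO replicate 1 to 1.21 in HKO replicate 2.

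Immune lists differed in direction. MHC class II genes, which present antigen on macrophages, dendritic cells and B cells, had a mean of -0.60 over 7 genes (camera adjusted p = 8.90e-05; adjusted p = 0.288 with an estimated correlation); H2-Aa was at -1.05 ± 0.23 and H2-Eb1 at -0.84 ± 0.21, with 5 genes past the threshold adjusted over the list alone and 0 over all genes. Inflammatory cytokines and receptors had a mean of -0.24 (camera adjusted p = 0.0238; adjusted p = 0.451 with an estimated correlation), with 0 genes past either threshold. That call was lost without Con replicate 1 (adjusted p = 0.0986), Con replicate 2 (mean -0.15, 0.233), HKO replicate 1 (0.115) or HKO replicate 3 (0.0839), the mean was -0.38 without Con replicate 3, and the arrays overlapped, with Con replicate 3 at -0.27 and HKO replicate 2 at -0.05 from the Con mean. The interferon list had a mean of 0.14 (camera adjusted p = 0.0129; adjusted p = 0.288 with an estimated correlation), with Ifit1 at 0.66 ± 0.14 and 4 genes past the threshold adjusted over the list alone and 0 over all genes. It did not pass without Con replicate 3 (mean 0.09, adjusted p = 0.139), and HKO replicate 1 (0.05) lay below Con replicate 2 (0.08). The acute phase list did not pass (-0.28, adjusted p = 0.123), with Saa2 at -1.64 ± 0.37 (adjusted p = 0.164), and passed without Con replicate 3 (-0.46, 0.000261) or HKO replicate 2 (-0.40, 0.0123), while it stood at -0.16 without HKO replicate 1 and -0.19 without Con replicate 1 or Con replicate 2.

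Stress and cell cycle lists were lower. Unfolded protein response genes had a mean of -0.26 over 22 genes (camera adjusted p = 2.05e-06; adjusted p = 0.206 with an estimated correlation) and 7 fell when adjusted over the list alone; the chaperone gene Hyou1 was at -0.51 ± 0.11 and Creld2 at -0.64 ± 0.15. Cell cycle genes had a mean of -0.32 over 22 genes (camera adjusted p = 8.46e-07; adjusted p = 0.206 with an estimated correlation), 8 fell when adjusted over the list alone, and the proliferation marker Mki67 was at -0.64 ± 0.12. Oxidative stress genes had a mean of -0.21 and a median of -0.13 (camera adjusted p = 0.00234; adjusted p = 0.280 with an estimated correlation), with Srxn1 at -0.66 ± 0.13 and 1 gene past the threshold adjusted over the list alone. Over all genes 0 members of these 3 lists passed. The immediate early and heat shock list did not pass (-0.03, adjusted p = 0.687; -0.08 without HKO replicate 3 and 0.01 without HKO replicate 1).

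Lists tied to Slug's family were also examined. Epithelial junction and keratin genes had a mean of 0.14 (camera adjusted p = 0.0133; adjusted p = 0.445 with an estimated correlation), with Krt8 at -0.49 ± 0.10 and Gjb2 at 0.37 ± 0.10, and 2 genes rose and 1 fell when adjusted over the list alone. That call was lost without Con replicate 1 (adjusted p = 0.0644), Con replicate 2 (0.0660) or HKO replicate 1 (0.0501), and Con replicate 3 (0.10) lay above HKO replicate 3 (0.08). Mesenchymal genes and the Snail, Zeb and Twist factors had a mean of -0.18 (camera adjusted p = 0.0201; adjusted p = 0.280 with an estimated correlation), with Vim at -0.56 ± 0.12 and Mmp14 at -0.62 ± 0.13, and 3 fell when adjusted over the list alone. The mesenchymal call was lost without Con replicate 2 (adjusted p = 0.0660). Over all genes 0 members of either list passed. Slug cofactors and histone modifiers did not pass (-0.10, adjusted p = 0.056). Pericentral (0.12) and periportal (0.14) genes did not pass, with Igfbp2 the periportal member that rose. The periportal mean was 0.27 without HKO replicate 3, where it passed (adjusted p = 0.0267), and -0.02 without HKO replicate 1, and pericentral genes passed without Con replicate 3 (0.16, adjusted p = 0.0315) or HKO replicate 1 (0.15, 0.0365) and stood at 0.07 without HKO replicate 2. Mean, median and test differed in sign for the xenobiotic, sinusoidal, female-biased, insulin signalling, adipocyte, lipoprotein and gluconeogenesis lists, none of which passed.

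**Figure D4:**
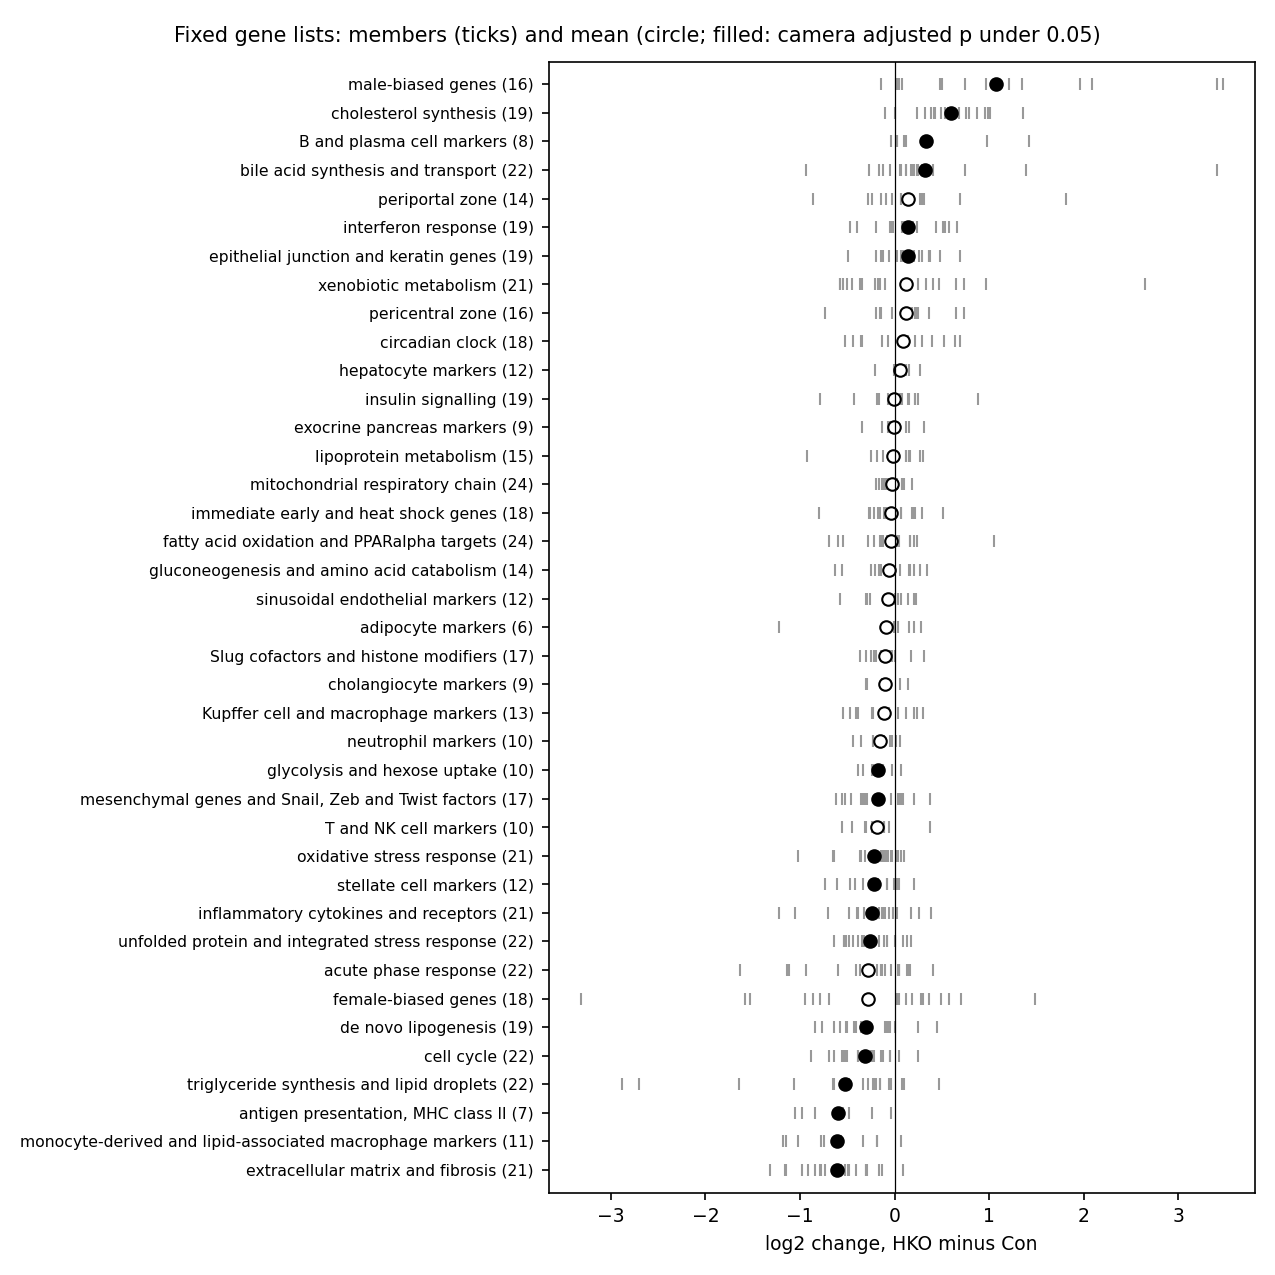
Grey ticks give the log2 change from Con to HKO of each measured member of 39 gene lists (number measured in brackets) and circles the mean, filled where camera's adjusted p with the preset correlation is under 0.05. The 18 filled lists run from -0.61 for the matrix list to 1.08 for male-biased genes, and 0 of them pass with an estimated correlation.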

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

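All settings here were chosen before the data were examined. The total count of genes past adjusted p 0.05 (45, with 20 higher and 25 lower) ranged widely: 138 (60 and 78) among genes above the median level, where fewer genes are tested, 215 (100 and 115) with a variance trend, 115 (57 and 58) at adjusted p 0.1, 4 (0 and 4) with every probe set tested on its own, and 0 (0 and 0) with Welch's statistic, where 3 arrays per group leave few degrees of freedom. Of the 45 genes, 41 were shared with the first setting and 45 with the variance trend. The cause of the other shifts was not tested. The second quantile normalization, centring, the lower-quartile filter, the mean of probe sets, the robust fit, array weights and the fold threshold gave 40 to 48 genes. Leaving out 1 array gave 4 to 32 genes in total, 0 to 16 higher and 4 to 16 lower, with fewer samples in the fit; only Con replicate 3 left the total within 1.5 times of 45.

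Snai2 kept its direction in every setting. Its change was -2.43 with an adjusted p of 0.578 by the Welch statistic, and leaving out 1 array gave -2.69 to -2.15, with -2.36, -2.39 and -2.45 no longer past the threshold; adjusted p over the alternatives ran from 0.000967 to 0.578. The replicate numbers shared by the groups paired the arrays at most weakly. Correlations of the deviations of same-numbered arrays were 0.0323, 0.0160 and 0.0214. Yet 6 of 6 arrays correlated best with their own number. Deviations from a group mean tie the arrays of that group to each other, so these 6 matches are not independent. They are a weak hint at most, and pairing stays open. With the replicate number as a block, 3 genes passed (0 higher, 3 lower), Snai2 stood at -2.43 with an adjusted p of 0.0540, and 19 lists passed.

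The count of lists (18) was 0 with an estimated correlation and 5 with fry, and 13 to 23 with 1 array left out; the calls of the inflammatory, epithelial, B and plasma cell, stellate, mesenchymal and interferon lists were each lost without at least 1 array, and the other 12 held. The lipogenesis mean stayed at -0.30, with an adjusted p of 0.387 with an estimated correlation and 0.114 with fry, and lay between -0.38 and -0.19 with 1 array left out. Signs reversed for 1 gene and for lists that did not pass as reported; most of these stood near 0, but the periportal mean was 0.14, and that list passed without HKO replicate 3 (0.274, adjusted p = 0.0267). Insulin signalling stood at 0.0170 after a second quantile normalization, 0.00179 after centring and 0.00607 with the mean of probe sets. With 1 array left out, ranges crossed 0 for insulin signalling (-0.0250 to 0.0127), Slc4a1 (-0.093 to 0.369), fatty acid oxidation (-0.0679 to 0.000532), lipoprotein (-0.0564 to 0.00594), respiratory chain (-0.0586 to 0.00675), immediate early (-0.0800 to 0.0145), periportal (-0.0206 to 0.274) and pancreas genes (-0.0478 to 0.0355). Signal near the arrays' floor limits what can be seen for dim genes.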

Other observations

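Chosen only after the result was seen were the families of the next paragraphs, all tests of an explanation except the other splits of the arrays and the vessel wall test, and conditions added later to those tests and to the vessel wall test (for comparisons of lists, the median of the comparison genes apart from the pattern by more than their SD; for the fasting genes, their median plus their SD below the size of the lipogenesis fall). Immunoglobulin genes stood higher in HKO. Of 22 measured immunoglobulin and joining chain genes, 14 were higher at an unadjusted p under 0.05 and 0 were lower, 0 passed limma's adjusted p over all genes, and the mean log2 change was 0.81 ± 0.13 (SE over members). Of the 22, 12 lay below the median level of all genes (mean change 0.59); the 10 above it had a mean change of 1.08, and 7 of these were higher at an unadjusted p under 0.05. The family was picked because members were seen to be high, so no test of it is given. The arrays differed: HKO replicate 2 lay 1.25 above the Con mean, HKO replicate 1 lay 0.57 and HKO replicate 3 lay 0.61 above it, and without HKO replicate 2 the mean change was 0.59. Igh-VS107 had means of 3.74 in Con and 5.77 in HKO and Igkj1 of 3.41 and 4.99; these Con means are below the median level and not shown to be above background. The B cell surface gene Cd79a stood at 0.12. Antibody genes are similar in sequence, and probe sets can share signal; of 6 further Ighm probe sets, 4 stood at 0.51 to 1.32 and 2 at -0.04.

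Annexins, membrane-binding proteins of which Anxa2 is one, had a mean of -0.46 ± 0.19 over 11 genes (SE over members, as for the families below). The mean was -0.71 over the 7 above the median level and -0.03 over the other 4. Anxa2 fell over all genes, 5 were lower and 0 higher at an unadjusted p under 0.05, and Anxa5 (-0.92) and Anxa1 (-1.02) came next in p. S100a10, the binding partner of Anxa2 and likewise chosen after its value was seen, fell as well (-0.87, adjusted p = 0.0344). Genes of tryptophan breakdown and NAD synthesis had a mean of 0.31 ± 0.12 over 11 genes, of which 4 were higher and 0 lower at an unadjusted p under 0.05. Afmid, kynurenine formamidase, was the member that rose (0.86, adjusted p = 0.0344). Nmrk1 (0.95, adjusted p = 0.154) and Acmsd (0.86, adjusted p = 0.0533) did not pass. Tdo2 (0.01), Kmo (0.02), Qprt (0.03) and Kynu (-0.12) changed little, so the mean does not show a rise of the whole route. Terminal complement genes had a mean of 0.48 ± 0.22 over 6 genes, with C8b the member that rose and C6 at 0.78 (adjusted p = 0.22).

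With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 45 genes and the highest other split 0; for lists it called 18 and the highest other 13. In each case 1 of 10 splits, the real one, reached the real count. Of 16010 probe sets with no gene name, 0 passed limma's adjusted p, with 651 higher and 544 lower at an unadjusted p under 0.05; of 1814 with several genes, 0 passed, with 51 higher and 59 lower.

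Male-biased genes were higher and Cyp2b13 was lower in HKO, although the labels give all mice as male. A female mouse among the controls was argued against by 3 Y-linked genes, whose mean in the lowest Con array lay 0.222 above that in the lowest HKO array. A larger share of hepatocyte RNA was first set against female-biased genes, which hepatocytes also make; the male-biased mean lay 1.36 ± 0.387 above theirs, past the bound set for that test, but the spread of the female-biased genes exceeded the distance of their median from the male-biased mean, which leaves that test undecided. Hepatocyte markers were then taken instead, after that value was seen. The male-biased mean lay 1.02 ± 0.288 (SE over genes) above theirs (0.878 to 1.23 with 1 array left out). The male-biased genes were picked for their rise, so that gap was largely set in advance and by itself decides nothing. Hepatocyte markers, not picked for their change, had a mean of 0.06 and did not pass as a list. They lay 0.16, 0.00324 and 0.00643 above the Con mean in HKO replicates 1 to 3, against 1.15, 1.31 and 0.78 for the male-biased list. These values argue against a larger hepatocyte share as the whole cause of the male-biased rise. An effect of hepatocyte Slug loss on genes that follow growth hormone, a difference in hormone state between litters, and the Cre transgene stay open. Each may contribute, and none was tested here. How the mice of each group were spread over litters is not given in the sources used here.

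Extracellular matrix and monocyte-derived macrophage genes were lower in HKO, by a mean of -0.59 over 31 genes. Fewer non-parenchymal cells of every kind would lower sinusoidal and Kupffer markers as much. The pattern lay -0.502 ± 0.0848 (SE over genes) from those (-0.595 to -0.415 with 1 array left out). Its lists were picked for their fall, but sinusoidal and Kupffer markers averaged only -0.09, which argues against an equal loss of every kind of cell. Some of these markers fell further: Lyve1 (-0.57), C1qa (-0.47), Cd68 (-0.40) and Pecam1 (-0.29), none past the threshold over all genes. In HKO, 5 of 13 Kupffer and 7 of 12 sinusoidal markers were higher. A smaller loss of some of these cells stays open. Less vessel wall and portal tract was tested against a bound written before its value was seen. The pattern lay -0.399 ± 0.0836 (SE over genes) from smooth muscle and portal fibroblast markers, past the bound written for that test. The 9 of the 19 markers above the median level of all genes averaged -0.20 and the 10 below it -0.19. Several of the 9 lay close to that median, such as Tagln (4.25 in Con) and Eln (4.24), so low signal is not excluded. Single markers differed: Myh11 (-0.58) and Cd34 (-0.55) fell about as much as the pattern. Of 10 smooth muscle markers 2 were higher in HKO, as were 3 of 9 portal fibroblast markers. The gap thus argues only weakly against less vessel wall and portal tract as the whole cause. Smooth muscle markers themselves averaged -0.24, so a smaller contribution stays open. A milder response to the diet in HKO livers is a candidate explanation with no test here.

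Lipogenesis genes were lower while cholesterol synthesis genes were higher in HKO. Less food before tissue was taken would lower both. The cholesterol mean lay 0.893 ± 0.112 (SE over genes) above the lipogenesis mean. The pattern was picked for these opposite directions, so that gap was set in advance and decides nothing. The HKO arrays lay 0.02, 1.21 and 0.56 above the Con mean in the cholesterol list, so a fall of both lists was not seen. For the lipogenesis list alone, 14 genes raised by fasting had a mean of -0.129 ± 0.0924 (SE over genes), below the 0.149 that test asked for. They went both ways (Ppargc1a 0.34, Pdk4 -0.55), so this argues only weakly against less food before tissue was taken. Without HKO replicate 2 the cholesterol mean was 0.289 ± 0.0629 (SE over genes) against 0.277 in the highest Con array. The other HKO arrays lay at 0.02 and 0.56 from the Con mean, a wider spread than that SE. An effect of HKO replicate 2 alone thus cannot be told apart from one of the group. Loss of Slug in hepatocytes may lower lipogenesis genes directly or through insulin or diet intake, and these arrays do not separate the routes.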
